A study of Mus musculus with 8 samples.

How the data were processed

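RNA from splenic B cells of Irf4 null mice (4 arrays) and wild-type littermates (4 arrays), strain C57BL/6, was labelled from 6 µg of total RNA and hybridised to 1 Affymetrix mouse array per sample, per the labels' protocols. The values are intensities on a linear scale, 1 per probe set, which the authors computed with MAS5, per the submitters' processing notes; the version and the scaling target are not given in the sources used here. MAS5 summarises each array on its own. In the deposited intensities the mean without the highest and lowest 2% of probe sets is 500.003 on every array, so the arrays were already scaled to 1 level and no further normalization was applied. The table holds 45101 probe sets and no detection calls, so a low signal cannot be told from background, and folds against a low signal are uncertain. No array columns held identical values.

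Probe sets were named from the platform annotation, which pairs 34958 probe sets with 1 gene symbol and 932 with several, and 9211 are unnamed here. Symbols were updated through gene identifiers to the RefSeq gene table of the assembly GRCm38.p6, which matched 34754 of the 34958. That table was used only for names and for which genes lie near each other, since the sources name no genome build, and no coordinates are printed. Probe sets with several symbols were tested and not named.

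The 64 control probe sets were left out, signals were taken as log2(signal + 16), and probe sets in the lowest 40% by mean log2 value over all 8 arrays were dropped (mean log2 up to 5.88, a signal of 42.9), which left 27022. The added 16 makes fold changes of dim probe sets smaller than on the raw scale. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with Benjamini-Hochberg adjustment over the 27022 probe sets and a threshold of 0.05. Fold changes are Irf4 null minus wild type, with standard errors from the fit. Each gene was represented by the probe set with the highest mean log2 value among those with exactly 1 symbol, which gave 11802 genes. Figures were drawn with matplotlib 3.10.9.

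Before the data were examined, 30 gene lists were fixed for B cell subsets, Notch, plasma cells, interferon, signalling, cell cycle, metabolism and markers of other cell types. Lists with at least 5 tested genes, 28 of the 30, were tested with camera at a preset correlation of 0.01 and adjusted over the 28. This test asks whether a list moves more than the other genes, so a list that does not pass may still have moved. Of these, 12 passed; with a correlation estimated from the data none passed, also with the Xist-high term, and with fry, which asks whether a list's genes move one way on balance, 6 passed. List counts are given over all probe sets tested and adjusted over the list alone. The median and the mean or test differ in sign for Notch pathway components, B cell receptor signalling, antigen presentation, migration and adhesion, NF-kappaB, apoptosis regulators and cytokine and TNF family genes, none of which passed. The rule for named genes was also fixed then. It takes Irf4, then the 12 largest rises and the 12 largest falls among called genes whose 4 Irf4 null values all lie on 1 side of the 4 wild-type values, then from each list up to 4 called members with the smallest adjusted p, or 2 members where none was called.

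The fit was tested on simulated data made from the real means and spreads of the 27022 probe sets, with 200 of them changed. It recovered 23.9% of 1.5-fold changes, 59.7% of 2-fold changes and 87.9% of 4-fold changes, and 1 of 115 calls was false. Of 28 simulated lists with 1 shifted by 0.5, camera called 2, the shifted list and 1 that was not shifted. The simulated noise was independent between genes and held no sex difference, unlike the real arrays. These rates of true and false calls may therefore not hold for the real data.

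Sex was read from Xist, with arrays over a signal of 1000 called Xist-high, after the data were seen. Fits with this term, within the Xist-high and Xist-low arrays, and with the mean of the 68 markers of other cell types as a covariate were added for that reason. Other alternatives were the pseudocount, the filter on dim probe sets, quantile normalization, a common median, other variance models, array weights, the replicate number as a block, each array left out in turn, a stricter threshold, the estimated correlation, fry, the mean of all probe sets of a gene, and other windows around Irf4. Intervals of medians are 95% bootstrap intervals from 10000 draws of genes, which are not independent. All 35 splits of the 8 arrays into 4 and 4 were fitted. The test of genes near Irf4 against windows elsewhere, and its rule, were set after the values were seen. No scanner files were used here.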

Results

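Gene expression was measured in mature B cells from the spleens of 12-week-old mice that lack Irf4 (Irf4 null, n = 4 arrays) and of their wild-type littermates (n = 4 arrays). Irf4 is a transcription factor of lymphocytes that is required for the formation of plasma cells. The cells were enriched with magnetic beads that removed other cell types, and RNA was hybridised to a mouse oligonucleotide array with 45101 probe sets. Every array had the same trimmed mean signal, 500.003, and median signals between 76.9 and 92.2. Correlations between arrays lay between 0.960 and 0.982 over the 27022 probe sets tested, and the number of arrays limits the precision. The labels do not say that each array came from a mouse of its own, so p-values measure the spread between these samples, which may be partly technical.

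The targeted gene was lower on every Irf4 null array. The brighter Irf4 probe set read 2035, 1720, 1779 and 2341 in wild type and 285, 259, 244 and 315 in Irf4 null, a log2 fold change of -2.76 ± 0.12 (SE; limma, adjusted p = 4.6e-06). The dimmer probe set read 120, 82.2, 155 and 120 in wild type and 7.30, 48.3, 29.7 and 60.7 in Irf4 null. The deleted part of the gene is not given in the sources used here, so either probe set may lie outside it, and signal left in Irf4 null arrays does not show an intact transcript.

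The sex of the mice is not in the labels, and sex-linked RNAs split the arrays differently from genotype. Xist, the RNA that coats the inactive X chromosome of females, gave signals of 17119 to 19652 on wild-type arrays 1, 3 and 4 and on Irf4 null array 1, and of 49.2 to 94.8 on wild-type array 2 and Irf4 null arrays 2, 3 and 4. The Y-linked Eif2s3y read 3216 to 4530 on the Xist-low arrays and at most 25.4 on the Xist-high arrays. Markers of other blood cells moved with the same split. Their mean over 68 genes was 7.73, 7.93, 7.81 and 8.02 (log2) on the 4 Xist-high arrays, and 9.15, 9.22, 9.50 and 8.63 on the 4 Xist-low arrays. The main counts are therefore also given with Xist-high as a term in the fit, a choice made after the data were seen.

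The comparison of Irf4 null with wild type asks which RNAs differ between the B cell preparations of the genotypes. In RNA of whole preparations, a changed share of B cell subsets cannot be told from a change within cells. In Irf4 null B cells 8 of 13 marginal zone B cell markers, 3 of 6 Notch targets and 15 of 21 interferon-stimulated genes rose. As lists all 3 moved up at a preset correlation between genes, and none passed at an estimated one (camera, adjusted p = 0.073, 0.073 and 0.0765). The RNA of the immunoglobulin A heavy chain, of the joining chain and of several genes of plasma cells and germinal centre B cells was lower. Igha fell by 6.80 ± 0.40 on the log2 scale and Jchain by 6.00 ± 0.47, while Dtx1 rose by 1.44 ± 0.10 and Oas1a by 1.41 ± 0.11 (SE, n = 4 and 4). In all, 543 probe sets were higher and 407 lower at an adjusted p below 0.05 (limma), which at 1 probe set per gene are 315 genes higher and 201 lower among 11802. With the Xist-high term 381 probe sets were higher and 256 lower, and 552 of the 950 called without the term were called again.

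Among the 12 largest rises that separated all 4 Irf4 null arrays from all 4 wild-type arrays, Adgrl2, an adhesion G protein-coupled receptor, rose by 2.96 ± 0.49 (adjusted p = 0.00736), Flacc1 by 2.90 ± 0.31 (adjusted p = 0.000573), and the transcription factor Maf by 2.84 ± 0.29 (adjusted p = 0.000427). Maf went from a signal of 435 ± 201 (SD) in wild type to 2937 ± 243 in Irf4 null, and its 4 other tested probe sets also rose. Tnfrsf19, a receptor of the TNF family, rose by 2.74 and the potassium chloride cotransporter Slc12a5 by 2.70. Tlr3, a sensor of double-stranded RNA, rose by 2.62 ± 0.21, the calmodulin regulator Pcp4 by 2.59, and Ackr3, an atypical receptor for the chemokine CXCL12, by 2.56. Iigp1, an interferon-inducible GTPase, rose by 2.41 and the actin-capping protein gene Tmod2 by 2.35. Tbx21, which encodes the transcription factor T-bet, rose by 2.30 ± 0.15 (adjusted p = 2.8e-05), and Ffar2, a receptor of short-chain fatty acids, by 2.26. Each of these 12 genes kept its call with the Xist-high term. Within the Xist-low arrays Adgrl2 (1.18, adjusted p = 0.14) and Tmod2 (2.02, adjusted p = 0.0713) did not pass. Tmod2 averaged 15.6 in wild type, below the dim level of 42.9, and Slc12a5, Tnfrsf19 and Flacc1 averaged 49.4 to 58.5, so the size of these 4 folds is uncertain.

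The 12 largest falls were led by genes of antibody secretion. Igha went from 6531 ± 5044 (SD) in wild type to 34.4 ± 13.3 in Irf4 null (adjusted p = 2.4e-05), and Jchain, whose protein joins IgA and IgM chains into polymers, from 5064 ± 5182 to 43.6 ± 12.1 (adjusted p = 8.0e-05). The wild-type spread was wide, from 3123 to 13981 for Igha, and the Irf4 null signals lay near the level of dim probe sets, a mean of 42.9, so the folds are uncertain in size. The secreted protein gene Crisp3 fell by 3.33 ± 0.33, and Kctd14 fell by 3.19 ± 0.22, with its 3 other tested probe sets also lower. Sdc1, the plasma cell surface proteoglycan CD138, fell by 2.69 ± 0.33 (adjusted p = 0.00137), also to a dim mean of 47.6. Hepacam2 fell by 2.62, the regulator of G protein signalling Rgs13 by 2.12, and the secreted glycoprotein gene Reln by 1.95. Sspn fell by 1.90, the transcription elongation factor Eaf2 by 1.85 and the phosphoinositide phosphatase Inpp4b by 1.83. Irf4 itself is the remaining gene of the 12. Inpp4b (adjusted p = 0.042) lost its call in 10 of 22 alternatives, Sspn in 2, Rgs13 within Xist-low and Eaf2 within Xist-high arrays.

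**Figure D1:**
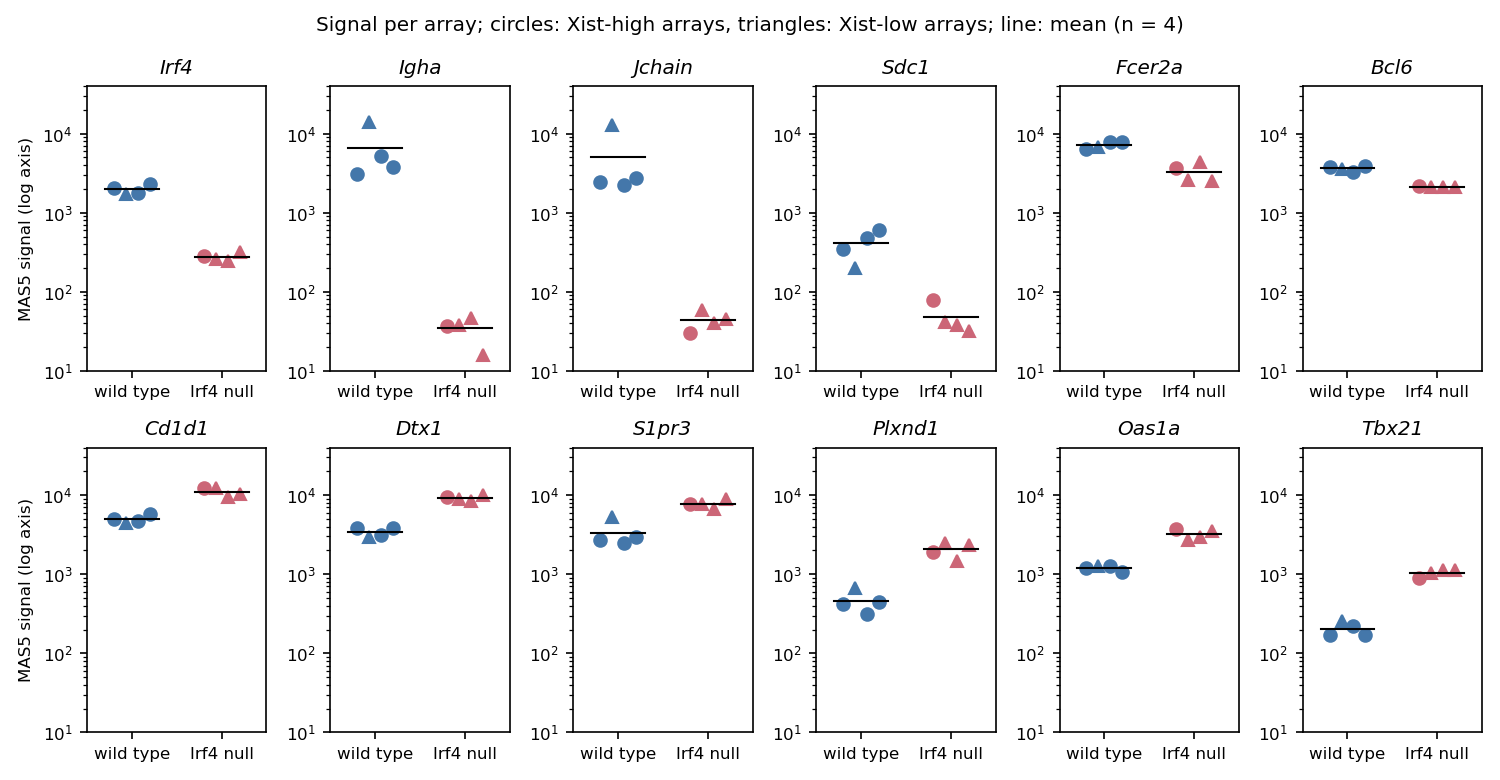
Signal of 12 genes on each array (vertical log axis, MAS5 signal) for wild type and Irf4 null, with circles for Xist-high and triangles for Xist-low arrays and a line at the mean of 4 arrays. In each panel the 4 Irf4 null arrays lie apart from the 4 wild-type arrays, as for Irf4 itself, which averaged 1969 in wild type and 276 in Irf4 null.

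Marginal zone B cells are a splenic subset that answers blood-borne antigens. Of 13 marginal zone markers tested, 8 rose, none fell and 5 did not pass, with a median log2 fold change of 1.12. Adjusted over the list alone, 10 rose, Cr2 and Notch2 among them, and Cd36 fell. The 5 that did not pass were Cr2 (0.28, limma, adjusted p = 0.157), Notch2 (0.22, adjusted p = 0.244), Cd9 (0.30, adjusted p = 0.46), Mzb1 (0.014, adjusted p = 0.968) and Cd36 (-1.07, adjusted p = 0.113). Plxnd1 rose by 2.14 ± 0.22 (adjusted p = 0.000452), Myof by 1.52 ± 0.17, Dtx1 by 1.44 ± 0.10 (adjusted p = 4.0e-05) and the lipid-presenting molecule gene Cd1d1 by 1.14 ± 0.10 (adjusted p = 0.000256). Cd1d1 signals were 5022 ± 591 (SD) in wild type and 11094 ± 1346 in Irf4 null. The sphingosine 1-phosphate receptor gene S1pr3 rose by 1.27 ± 0.20. The list as a whole moved up (camera, adjusted p = 2.2e-09; adjusted p = 0.073 with an estimated correlation). Its median was 1.24 within Xist-high and 0.63 within Xist-low arrays. With the Xist-high term 8 rose and 1 fell, the scavenger receptor gene Cd36 (-1.53, adjusted p = 0.0111), singled out after its value was seen. Of 7 follicular markers 1 fell, Fcer2a, the low-affinity IgE receptor CD23, by 1.17 ± 0.17 (adjusted p = 0.003). In all 2 fell when adjusted over the list alone. That list moved down with a median of -0.28 (camera, adjusted p = 0.00147; adjusted p = 0.454 with an estimated correlation), and its median was -0.062 with the Xist-high term (adjusted p = 0.047; adjusted p = 0.435 with the term and an estimated correlation).

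Of 6 Notch targets tested, 3 rose and 3 did not pass, also when adjusted over the list alone. Hes5, a basic helix-loop-helix repressor, rose by 1.95 ± 0.30 and Asb2 by 1.94 ± 0.30 (adjusted p = 0.00516 for both), and Dtx1 is the third. Dtx1 and Asb2 also belong to the marginal zone list, so the lists are not independent. The list moved up with a median of 0.94 (camera, adjusted p = 0.000208; adjusted p = 0.073 with an estimated correlation). Among 19 components of the Notch pathway 1 passed: Fbxw7, which marks active Notch for degradation, fell by 0.50 ± 0.10 (adjusted p = 0.0206), and 2 fell when adjusted over the list alone. That list did not pass (camera, adjusted p = 0.244).

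Interferon-stimulated genes are switched on in cells that respond to interferons. Of 21 tested, 15 rose, none fell and 6 did not pass; 20 rose when adjusted over the list alone, and 17 rose with the Xist-high term. Usp18 rose by 1.60 ± 0.19, Oas1a by 1.41 ± 0.11 (adjusted p = 8.0e-05), Oasl2 by 1.30 ± 0.15 and Ifit1 by 1.26 ± 0.15. Oas1a signals were 1200 ± 99.9 (SD) in wild type and 3220 ± 464 in Irf4 null. The list median was 1.11 (camera, adjusted p = 2.9e-17; adjusted p = 0.0765 with an estimated correlation). Among 13 interferon regulatory factors and partners, 1 rose, Irf7, by 1.09 ± 0.14 (adjusted p = 0.00181), which is also on the interferon-stimulated list. In all 2 rose when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.567). Of 13 Toll-like receptors and adaptors Tlr3 alone rose, also when adjusted over the list alone, and the list moved up with a median of 0.17 (camera, adjusted p = 0.013; adjusted p = 0.146 with an estimated correlation).

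Of 13 plasma cell genes, 3 fell, none rose and 10 did not pass, also when adjusted over the list alone. Jchain, Sdc1 and Eaf2 fell, while the list median was only -0.095 (camera, adjusted p = 0.00845; adjusted p = 0.309 with an estimated correlation). Of 4 immunoglobulin genes tested, too few for a test of the list, 3 fell, Igha, Ighg3 by 1.08 ± 0.15 (adjusted p = 0.00273) and Iglv1 by 0.48 ± 0.10 (adjusted p = 0.0222); all 4 fell when adjusted over the list alone. Of 16 endoplasmic reticulum chaperones and unfolded protein response genes, Pdia4 alone passed and rose by 0.75 ± 0.13 (adjusted p = 0.0106), also when adjusted over the list alone. The chaperone list did not pass (camera, adjusted p = 0.244).

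Of 7 germinal centre genes, 2 fell and 5 did not pass; 3 fell when adjusted over the list alone. Bcl6, the transcriptional repressor that germinal centre B cells need, fell by 0.78 ± 0.07 (adjusted p = 0.00028), from 3656 ± 265 (SD) to 2126 ± 32.8, and Rgs13 fell by 2.12 ± 0.25 (adjusted p = 0.00123). The list median was -0.58 (camera, adjusted p = 0.00147; adjusted p = 0.0765 with an estimated correlation). Of 11 transcription factors of B cell identity, Bach2 fell by 0.58 ± 0.08 (adjusted p = 0.00352) and Mef2c by 0.55 ± 0.11 (adjusted p = 0.0194); 3 fell when adjusted over the list alone. That list moved down with a median of -0.20 (camera, adjusted p = 0.00147; adjusted p = 0.448 with an estimated correlation), and its median was -0.076 with the Xist-high term (adjusted p = 0.047; adjusted p = 0.272 with the term and an estimated correlation). Of 9 genes of precursor and immature B cells, 3 fell, Sox4 by 0.94 ± 0.14 (adjusted p = 0.00435), Vpreb3 by 1.06 ± 0.22 and Cd93 from a signal of 837 ± 370 (SD) to 391 ± 63.8 (adjusted p = 0.0431); 1 rose and 3 fell when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0874). With the Xist-high term it passed downward, with a median of -0.40 against -0.076 without (camera, adjusted p = 0.00703; adjusted p = 0.2 with the term and an estimated correlation). None of the other tested probe sets passed for Sox4, Cd93, Dtx1, Tnfrsf19, Ighg3, Itgal, Bmf, Prf1 or Nusap1.

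**Figure D2:**
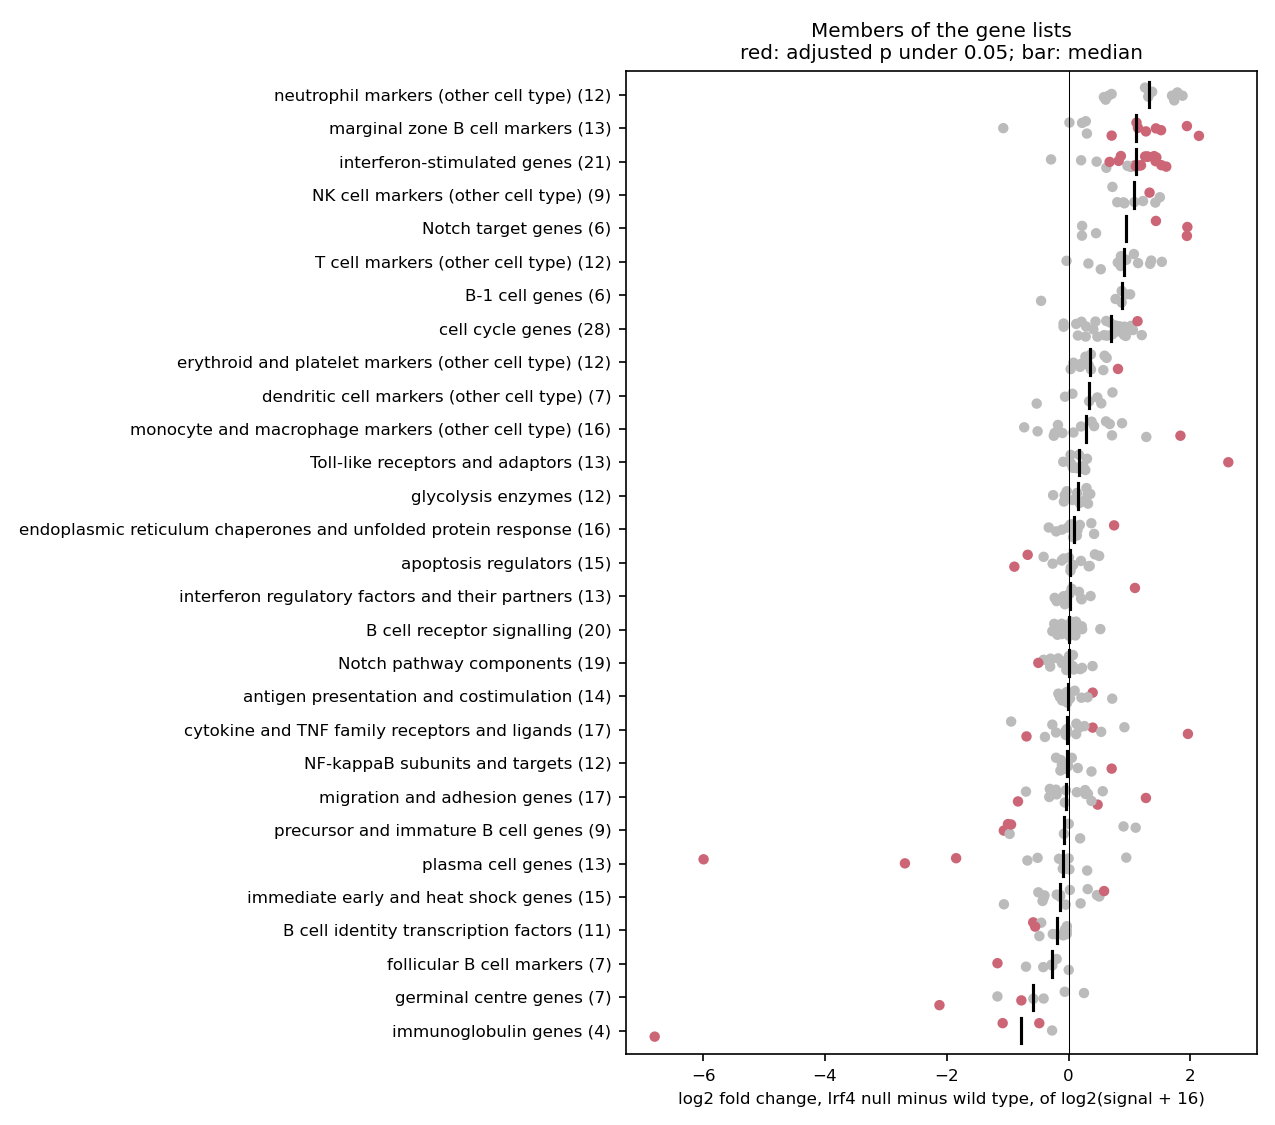
Log2 fold change of every tested member of each gene list (horizontal axis, Irf4 null minus wild type; number tested in brackets; sex-linked genes left out), in red where the adjusted p is below 0.05 and grey otherwise, with a bar at the list median. The marginal zone and interferon-stimulated lists have medians of 1.12 and 1.11, and neutrophil markers, with a median of 1.32, hold no gene that passed.

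None of the lists of signalling, survival and metabolism passed, and most of their members did not pass. Over all 11802 genes 315 were called higher and 201 lower. The migration and the cytokine lists, of 17 genes each, held 2 higher and 1 lower, a larger share. A list whose members move both ways can fail to pass as a list. Among 20 genes of B cell receptor signalling none passed, also when adjusted over the list alone (limma; 4 had an unadjusted p below 0.05). Cd72 had a log2 fold change of 0.52 ± 0.15 (adjusted p = 0.0988) and Bcl10 of -0.24 ± 0.07 (adjusted p = 0.104), and the list did not pass (camera, adjusted p = 0.771). With the Xist-high term Cd72 passed, at 0.69 (limma, adjusted p = 0.033). In antigen presentation and costimulation, 14 genes, Cd40 rose by 0.40 ± 0.07 (adjusted p = 0.0132), 2 rose when adjusted over the list alone, and camera gave an adjusted p of 0.655. Of 17 cytokine and TNF family genes, Il10 rose by 1.96 ± 0.33 (adjusted p = 0.00877) from a dim wild-type mean of 41.8, which leaves the fold uncertain, Cd40 rose, and Tnfrsf13c, the receptor of the survival factor BAFF, fell by 0.69 ± 0.14 (adjusted p = 0.0244). In all 2 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.981). Of 17 migration and adhesion genes, S1pr3 and the integrin gene Itgal rose, Itgal by 0.48 ± 0.10 (adjusted p = 0.0229), and the chemokine receptor gene Cxcr4 fell by 0.83 ± 0.19 (adjusted p = 0.0361). In all 4 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.981). Of 12 NF-kappaB subunits and targets Traf1 rose by 0.71 ± 0.13 (adjusted p = 0.0117), and 2 rose when adjusted over the list alone (camera, adjusted p = 0.981). Of 15 apoptosis regulators the survival gene Bcl2 fell by 0.67 ± 0.14 (adjusted p = 0.0248) and the death-promoting Bmf by 0.89 ± 0.16 (adjusted p = 0.0127). In all 1 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.814). Of 15 immediate early and heat shock genes Nr4a1 rose by 0.58 ± 0.14 (adjusted p = 0.0487); 2 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 0.526). Of 12 glycolysis enzymes none passed (limma; 3 at an unadjusted p below 0.05) and 2 rose when adjusted over the list alone (camera, adjusted p = 0.18), with Pgk1 at 0.32 ± 0.09 (adjusted p = 0.0715) and Ldha at 0.31 ± 0.09 (adjusted p = 0.0964). Of 6 B-1 cell genes none passed (limma; 3 at an unadjusted p below 0.05) and 2 rose when adjusted over the list alone (camera, adjusted p = 0.0551), with Zbtb32 at 0.77 ± 0.22 (adjusted p = 0.0888) and Spn at 0.87 ± 0.27 (adjusted p = 0.114).

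Cell cycle genes and markers of neutrophils, NK cells and T cells were higher in Irf4 null as lists at the preset correlation, and none of these 4 lists passed at an estimated one. Of 28 cell cycle genes Nusap1, a mitotic spindle gene, rose by 1.13 ± 0.25 (adjusted p = 0.0336), and 15 rose when adjusted over the list alone. The list median was 0.70 (camera, adjusted p = 2.1e-07; adjusted p = 0.454 with an estimated correlation) and 0.29 with the Xist-high term, where the list still passed upward (adjusted p = 0.000323; adjusted p = 0.435 with the term and an estimated correlation). Relative to the wild-type mean, the cell cycle list stood at 0.64 on wild-type array 2 and at 0.23 on Irf4 null array 1, and at 0.67 to 0.83 on the other Irf4 null arrays. Neutrophil markers had a median of 1.32 with none of 12 past the threshold (limma; 0 at an unadjusted p below 0.05), also when adjusted over the list alone (camera, adjusted p = 0.00756; adjusted p = 0.673 with an estimated correlation), and of 0.20 with the Xist-high term, where the list did not pass (adjusted p = 0.737). Elane was at 1.31 ± 0.63 (adjusted p = 0.325) and Cxcr2 at 0.71 ± 0.32 (adjusted p = 0.298). Of 9 NK cell markers the pore-forming protein gene Prf1 rose by 1.33 ± 0.24 (adjusted p = 0.0122), and 5 rose when adjusted over the list alone. The list median was 1.08 (camera, adjusted p = 0.000208; adjusted p = 0.454 with an estimated correlation). With the term it was 0.57 and the list still passed upward (adjusted p = 0.00241; adjusted p = 0.435 with the term and an estimated correlation). Of 12 T cell markers none passed (limma; 4 at an unadjusted p below 0.05), also when adjusted over the list alone, with Cd3g at 1.36 ± 0.46 (adjusted p = 0.147) and Cd3d at 1.53 ± 0.58 (adjusted p = 0.196). The list median was 0.90 (camera, adjusted p = 0.0119; adjusted p = 0.634 with an estimated correlation). With the term it was 0.25 and the list did not pass (adjusted p = 0.224).

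The remaining lists of other cell types did not pass. Of 16 monocyte and macrophage markers Spic, a transcription factor of red pulp macrophages, rose by 1.84 ± 0.27 (adjusted p = 0.00395), also when adjusted over the list alone (camera, adjusted p = 0.244); the list median was 0.29, and -0.30 with the Xist-high term, where the list passed downward (camera, adjusted p = 0.029; adjusted p = 0.435 with the term and an estimated correlation). Of 12 erythroid and platelet markers the platelet chemokine gene Ppbp rose by 0.81 ± 0.19 (adjusted p = 0.0415), also when adjusted over the list alone (camera, adjusted p = 0.0551). Of 7 dendritic cell markers none passed (limma; 1 at an unadjusted p below 0.05), also when adjusted over the list alone (camera, adjusted p = 0.525), with Itgax at 0.72 ± 0.23 (adjusted p = 0.13) and Xcr1 at 0.47 ± 0.30 (adjusted p = 0.48). With the Xist-high term 1 of the 7 dendritic cell markers fell. None of the 4 sex-linked genes tested, too few for a test of the list, passed between the genotypes, also when adjusted over the list alone. Their median was 2.55, with Xist at -3.85 ± 2.02 (adjusted p = 0.372) and Uty at 2.30 ± 1.13 (adjusted p = 0.338).

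**Figure D3:**
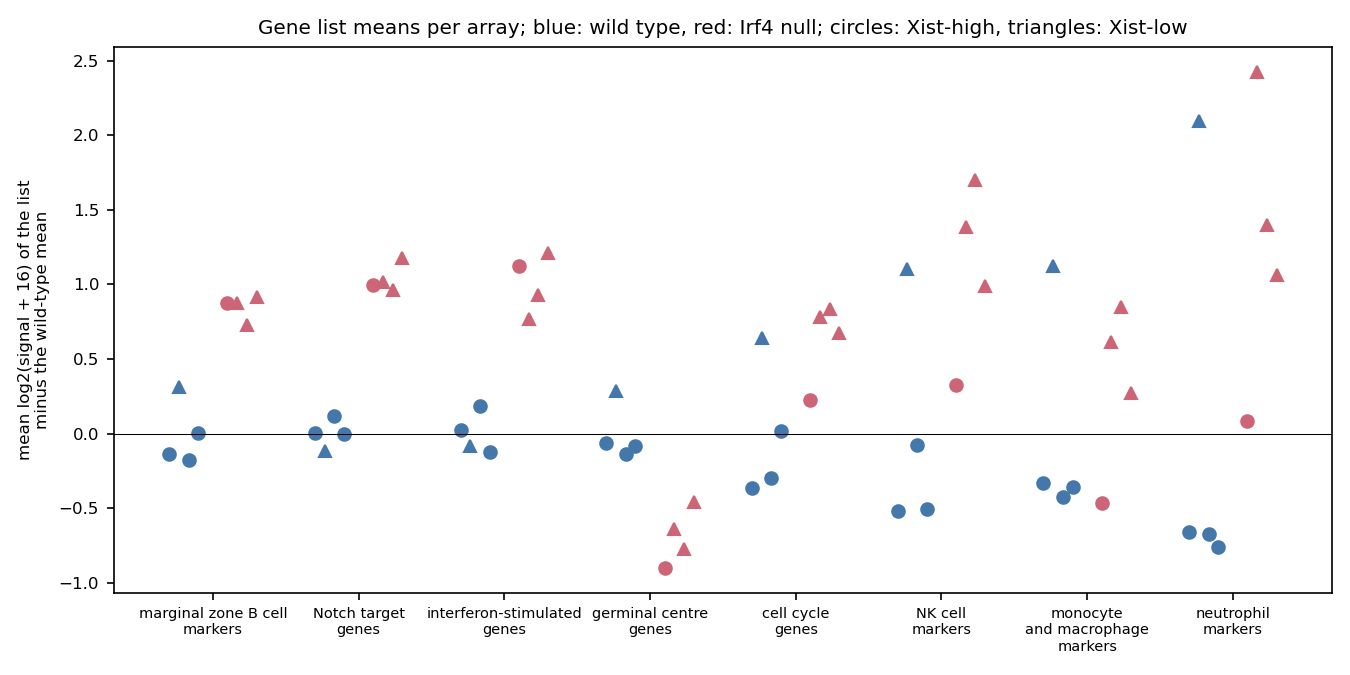
Mean log2(signal + 16) of 8 gene lists on each array, relative to the wild-type mean (vertical axis), with wild type in blue, Irf4 null in red, circles for Xist-high and triangles for Xist-low arrays. Marginal zone, Notch target, interferon-stimulated and germinal centre lists part by genotype, whereas neutrophil markers stand at 2.10 on the Xist-low wild-type array 2 and at 0.082 on the Xist-high Irf4 null array 1.

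Within the Xist-high arrays, 170 probe sets were higher and 85 lower, and within the Xist-low arrays 155 were higher and 109 lower, with 1 array on a side in each, which is taken to vary as the others do. A difference in genotype effect between Xist-high and Xist-low arrays can hardly pass in this design (limma interaction, 0 of 27022 after adjustment and 2038 at an unadjusted p below 0.05), so such differences stay open; Adgrl2 had 3.49 within Xist-high and 1.18 within Xist-low arrays, and Asb2 2.32 and 0.90. Fbxw7, Vpreb3, Iglv1, Mef2c, Itgal, Cxcr4, Bcl2, Tnfrsf13c, Nr4a1 and Ppbp kept their direction but not their call with the Xist-high term. Some of their log2 fold changes were nearly the same with the term, as for Bcl2 (-0.67 with and without) and Iglv1 (-0.49 with, -0.48 without), and others were smaller, as for Vpreb3 (-0.81 with, -1.06 without) and Tnfrsf13c (-0.50 with, -0.69 without). Over all 22 alternatives Ppbp lost its call in 14, Cxcr4 and Nr4a1 in 13, Itgal in 12, Cd93 in 11, Nusap1, Iglv1, Mef2c and Vpreb3 in 10, and Bcl2, Fbxw7 and Tnfrsf13c in 9.

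Genes near Irf4 were compared with all others, because a segment of the donor strain can stay around a targeted gene. Within 5 Mb of Irf4, 3 of 30 genes were called, against 511 of 11712 elsewhere (odds ratio 2.44, 95% interval 0.471 to 7.95, two-sided Fisher's exact test, p = 0.142). Within 2 Mb 2 of 12 genes were called (odds ratio 4.38, p = 0.0945, Fisher's exact test). Within 10 Mb 8 of 72 genes were called (odds ratio 2.76, p = 0.0131), Cmah, Sox4, Carmil1, H3c7 and Gm11342 lower and Dusp22, Gmnn and Serpinb9 higher, and within 20 Mb 17 of 146 (odds ratio 2.94, p = 0.000216, Fisher's exact test). Apart from Sox4, these genes were named after their values were seen.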

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

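The Xist-high term and the test of antibody-secreting cell genes were chosen after the results they bear on had been seen in part. A single array stood apart in 12 of 148 groups of 4 values tested for the named genes, where chance gives about 1 in 20; the number in brackets is the array's gap to its neighbour over the range of the 4 values. Xist stood apart on wild-type array 2 (0.975) and Irf4 null array 1 (0.905), and Uty on the same arrays (0.845 and 0.844), which are the arrays whose sex differs from the rest of their group. On wild-type array 2, Jchain was high at 12829 against 2222 to 2767 on the others (0.875), Eaf2 was high at 524 (0.935) and Vpreb3 was low at 1953 (0.902). On Irf4 null array 1, Sspn was low at 49.1 (0.872) and Nusap1 low at 991 (0.864). Flacc1 was low at 16.7 on wild-type array 1 (0.916), Eaf2 low at 47.2 on Irf4 null array 2 (0.906) and Nr4a1 high at 1187 on wild-type array 3 (0.847).

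The number of called probe sets was weighed first: the real split gave 950 and was the only 1 of 35 splits with as many. A split drawn at random would rank first in 1 of 35 cases, so chance division of the arrays is argued against but not excluded. The highest other split gave 774 and divides the arrays by Xist, while the next gave 2, so sex, or what went with it in these preparations, is a structure of the samples nearly as large as genotype. Over the 950 called probe sets the median ratio of fold changes with and without the Xist-high term was 0.937 (95% interval 0.926 to 0.947). This ratio cannot decide whether unequal sex is the whole cause, because the probe sets were picked as called without the term. An RNA that follows sex alone varies widely within each genotype and can hardly be called in that fit. Xist (-3.85 ± 2.02, limma, adjusted p = 0.372) and Uty (2.30 ± 1.13, adjusted p = 0.338) were not called. Only 552 of the 950 kept their call with the term. With 1 array of the rarer sex in each genotype, a sex effect on single genes stays open.

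The lower plasma cell genes were weighed second. A lesser carry-over of all other cells into the Irf4 null preparations would lower the 68 markers of other cell types. Their median log2 fold change was 0.66 (95% interval 0.53 to 0.84), which argues against it for the arrays as they stand. But these markers moved with the Xist split, which is uneven between the genotypes, so that median is not an effect of genotype alone. With the Xist-high term the medians were 0.57 for NK cell, 0.25 for T cell and 0.20 for neutrophil markers. They were -0.054 for erythroid and platelet, -0.13 for dendritic cell and -0.30 for monocyte and macrophage markers. A lesser carry-over of some cell types among arrays alike in Xist stays open. Fewer antibody-secreting cells among the purified cells may account for the falls: 10 tested genes of such cells had a median of -0.59 (95% interval -3.54 to -0.095). Igha, Jchain and Sdc1 had been seen before the test was set. Without them the other 7 had a median of -0.16 (-0.68 to -0.075), and of these Ighg3 alone passed its own test. Tnfrsf17, Ighg1, Ighg2b and Ighg2c of the set were not tested. On wild-type array 2 Igha (13981) and Jchain (12829) were the highest of the wild-type arrays and Sdc1 (198) the lowest, so these 3 did not move together there. Markers such as Xbp1, which other B cells also express, would hide a small share, lower RNA per cell was not tested, genes are not independent so the intervals are narrow, and the antibodies of the depletion are not given in the sources used here.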

How the results depend on the processing

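The fits with Xist-high arrays and with the other-cell covariate were added after the data were seen. Irf4 kept its direction and call in all 22 alternatives (log2 fold change from -2.83 to -2.58, limma, highest adjusted p 0.000372). None of the 60 called named genes changed direction, and 27 kept their call in every alternative that tested them. Of these 27, Reln, Sdc1, Slc12a5 and Tnfrsf19 were tested in 21 alternatives, because they were dropped with the lowest 60% left out. The counts of probe sets called higher and probe sets called lower, 543 and 407, became 355 and 200 without the variance trend, 1001 and 745 with array weights, 213 and 117 at a threshold of 0.01, and 226 and 94 with a 2-fold change required. They were 170 and 85 within the Xist-high arrays and 155 and 109 within the Xist-low arrays, fits with fewer arrays per contrast. The lower count was 256 with the Xist-high term and 266 with the other-cell covariate. Leaving out 1 array gave 283 to 1297 higher and 183 to 875 lower. Both highest counts came without wild-type array 2 (2172 in all). Without wild-type array 1, 3 or 4 the total was 525, 561 and 533, and without Irf4 null array 2 or 4 it was 504 and 466. A common median moved the share of higher calls from 57.2% to 47.8%. Whether the replicate numbers pair the arrays cannot be told, because the correlations of same-numbered arrays went with Xist. Deviations correlated at 0.237 and 0.277 for numbers 1 and 2, where both arrays were alike in Xist. They correlated at -0.030 and -0.081 for numbers 3 and 4, where 1 array was Xist-high and the other Xist-low. With the number as a replicate block 690 were higher and 478 lower, 838 of the 950 among them. Of 28 lists 12 moved, 0 with an estimated correlation (adjusted p from 0.073 upward), 0 with it and the Xist-high term together (from 0.0783 upward) and 6 with fry; leaving out 1 array gave 11 to 17. With the lowest 60% left out, germinal centre and B-1 lists had too few genes to test. The marginal zone, Notch target and interferon-stimulated lists were called in every alternative at the preset correlation and with fry, and in 8 of 8 fits without 1 array. T cell markers lost their call without Irf4 null array 3, and neutrophil markers without Irf4 null array 2. Of list medians, those of these lists turned: monocyte and macrophage markers (-0.30 with the Xist-high term, -0.59 within Xist-low arrays, -0.30 with the covariate), neutrophil markers (-0.49 within Xist-low arrays), T cell markers (-0.015 within Xist-high arrays), dendritic cell markers (-0.13 with the term, -0.22 within Xist-high and -0.11 within Xist-low arrays, and below 0 with the covariate), erythroid and platelet markers (-0.054 with the term, -0.070 within Xist-high arrays, -0.35 with the covariate, and below 0 without Irf4 null array 3), and, within Xist-low arrays, B-1 cell genes (-0.074), endoplasmic reticulum chaperones (-0.092) and glycolysis enzymes (-0.091). The medians near 0 of Notch components, B cell receptor signalling, interferon regulatory factors, apoptosis, migration, cytokine, antigen presentation, NF-kappaB and precursor genes also crossed 0 in some alternatives. The precursor list passed downward with the Xist-high term, within both strata, with the covariate, with the lowest 60% left out and without wild-type array 3, all at the preset correlation and with 1 array on a side in each stratum; it did not pass at an estimated correlation without the term (0.454) or with it (0.2), nor with fry (0.127). The odds ratio near Irf4 was 2.76 at 10 Mb, 2.94 at 20 Mb, 4.39 for 50 genes on each side and 4.06 for 100, all past the threshold. It was 2.44 at 5 Mb, 4.38 at 2 Mb (p = 0.0945), 3.65 for 25 genes on each side (p = 0.123) and 1.94 at 5 Mb without the filter on dim probe sets (p = 0.212, Fisher's exact test), none of which passed. For each of these shifts the cause was not tested. Without detection calls, the arrays limit what can be said of genes near background, such as Igha in Irf4 null.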

Other observations

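The gene families and genes in this part were chosen after their values were seen, as was the test against windows elsewhere in the genome. A family picked this way gives no independent test, so no test of a whole family is given. Of 10 interferon-inducible GTPases tested, which act against intracellular microbes, 7 rose, also with the Xist-high term, among them Gbp6 by 1.52 ± 0.17 (limma, adjusted p = 0.000742) and Gbp7 by 1.47 ± 0.16 (adjusted p = 0.000579), with a median of 0.70; Iigp1 is also among the 12 largest rises and Gbp2 on the interferon-stimulated list. Of 14 host genes of small nucleolar RNAs tested, 7 rose and 7 did not pass, with Zfas1 at 0.90 ± 0.13 (adjusted p = 0.00424) and Gas5 at 0.38 ± 0.07 (adjusted p = 0.0182), and 13 of 14 lay above 0; 3 were called with the term. Of 19 genes of sterol synthesis and its control, 4 fell, Cyp51 by 0.64 ± 0.13 (adjusted p = 0.0204), Sqle by 0.61 ± 0.14 (adjusted p = 0.0422), Srebf2 by 0.53 ± 0.13 (adjusted p = 0.049) and Insig1 by 0.45 ± 0.09 (adjusted p = 0.0194), and 15 of 19 lay below 0, with a median of -0.23. With the Xist-high term 4 were again called, with Hmgcs1 (adjusted p = 0.0244) in and Srebf2 (adjusted p = 0.154) out.

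With genotype in the fit, Xist-low arrays had 502 probe sets higher and 56 lower than Xist-high arrays (limma). Of the 372 genes called, 13 are on X or Y. The others included neutrophil granule genes, where Xist-high minus Xist-low was -3.21 for Ltf, -2.99 for Camp, -2.98 for Lcn2 and -2.94 for Ngp on the log2 scale. It was -1.71 ± 0.14 for the macrophage growth factor receptor gene Csf1r and -1.67 ± 0.15 for the granzyme gene Gzma. Neutrophil markers had 10 of 12 genes lower on Xist-high arrays, monocyte and macrophage markers 9 of 16, NK cell markers 6 of 9, dendritic cell markers 3 of 7, B-1 cell genes 3 of 6 and cell cycle genes 12 of 28. Beside these, 2 of 7 follicular B cell markers were higher on Xist-high arrays. As lists, neutrophil, NK cell, T cell and cell cycle genes were lower on Xist-high arrays at the preset correlation. None of them passed at an estimated one (camera, adjusted p = 0.0983, 0.0983, 0.385 and 0.0983). Monocyte and macrophage, dendritic cell, erythroid and platelet, B-1, chaperone and glycolysis lists were also lower. Follicular, B cell receptor, B cell identity and antigen presentation lists were higher (camera, adjusted p = 1.4e-05, 2.6e-05, 0.00025 and 0.015). These too did not pass at an estimated correlation (adjusted p from 0.0875 upward). T cell markers did not follow the split on every array, at 0.43 on Xist-high wild-type array 3 and 0.27 on Xist-low wild-type array 2.

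The called genes near Irf4 were the third pattern weighed. A donor segment around the targeted gene may contribute: the odds ratio of called genes was 2.44 within 5 Mb, with a 95% interval of 0.471 to 7.95. Called genes also cluster elsewhere. In runs of 20 consecutive tested genes the highest count of called genes was 6. It was reached on chromosome 13 from Carmil1 to Dusp22, both within 10 Mb of Irf4, and also on chromosomes 3 and 5. Among windows centred on every tested gene the share near Irf4 lay at percentile 92.8 for 5 Mb, 97.2 for 10 Mb and 99.5 for 20 Mb. The rule for this test, that all 3 widths count, was set after these values were seen; by the 20 Mb width alone, the first rule, ordinary clustering would have been argued against. A donor segment and ordinary clustering cannot be told apart here, because 30 genes lie within 5 Mb, the donor strain is not given in the sources used here, and overlapping windows are not independent.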
